A study of Oryctolagus cuniculus with 10 samples.

How the data were processed

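RNA was measured by sequencing in 10 libraries from the lateral part of the left upper lung lobe of New Zealand rabbit fetuses. Per the labels' protocols, RNA was treated with DNase, purified on columns and made into libraries by standard Illumina methods; strandedness, read length and batch are not given in the sources used here. The submitters' processing notes name kallisto 0.42.2.1, a tool that assigns reads to transcripts without full alignment, edgeR without a version, and the rabbit build OryCun2.0. The notes give no role or order of these tools. How transcript estimates were summed to genes, rounded and filtered is not given in the sources used here.

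The deposited table holds 13429 Ensembl rabbit gene identifiers and 1 column per library. Its name speaks of CPM, but its values are whole numbers that sum to between 16383835 and 22239034 per library, so they are not scaled to a common total. Even values make up 50.3% of all entries, and the lowest sum of a gene over the libraries is 5. The values were therefore treated as estimated counts that the authors deposited as whole numbers, and no rounding was needed. A test on log2 CPM had been planned in case the table held CPM. For counts, the plan named edgeR's quasi-likelihood test, and that test was used. Intervals and p-values rest on these counts as the authors made them. Reads shared by near-identical gene copies, or by overlapping genes, may have been divided between them, so values of such genes are uncertain.

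None of the 13429 identifiers matched a symbol in the reference table of 38822 rabbit genes. That table belongs to another assembly and lists no Ensembl identifiers, so no match was possible. Genes are therefore given by identifier, without symbol, position or function. The 37 gene lists, like the comparisons, the filter and most alternatives, were chosen before the data were examined. The lists (alveolar, airway, endothelial, muscle, matrix, cell cycle, growth factor, lipid, blood, liver and other lists) could not be applied. The rule for named genes took, per comparison, the 8 largest changes in each direction among genes with a symbol, an adjusted p under 0.05, no overlap between the groups and at least 5 CPM, plus 8 genes by symbol. No gene has a symbol here, so the rule names none. In its place the text names every gene called by edgeR, and 2 genes that did not pass; these choices were made after their values were seen. No column of the table was left unused.

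Libraries were grouped by their source labels into control (n = 3), hernia (n = 2), occlusion (n = 2) and hernia with occlusion (n = 3). The labels do not state how fetuses were distributed over litters. Library titles share the stem M83 between a control and a hernia with occlusion library, and the stem M88 between an occlusion and a hernia with occlusion library. Both hernia libraries have stems apart from the rest, M38 and M39, while the stems of all other libraries run from M83 to M98. The meaning of the stem is not given, so it entered only an alternative fit. A difference that follows these stems cannot be told apart from an effect of the hernia alone.

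Genes with at least 1 CPM in at least 2 libraries were tested, which kept 13379 genes and removed 50. Counts were scaled by edgeR's trimmed mean of M-values (edgeR 4.0.16, R 4.3.3). A quasi-likelihood model with 1 mean per group was fitted to all 10 libraries, leaving 6 residual degrees of freedom, because groups of 2 are too small for a spread of their own. There were 8 comparisons: 5 between groups, the interaction of hernia and occlusion, and the effects of occlusion and of hernia averaged over the other factor. Benjamini-Hochberg adjusted p under 0.05 was called, within each comparison. Standard errors were derived from the log2 change and the F statistic. CPM values in the text were computed from the counts with the scaled library sizes. Principal components, correlations and scores used log2(CPM + 0.5). The p-values measure the spread between these libraries, which the labels place in separate samples without saying more about their origin.

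Agreement of 2 comparisons was measured as Pearson's r and Spearman's rho of log2 changes across genes, which are not independent replicates. Chance values came from 100 simulations of unchanged groups, with negative binomial counts drawn independently for each gene from its mean and dispersion. An occlusion score was built from the 200 genes with the lowest p in each direction for hernia with occlusion against hernia. That fit used only the 5 libraries with a hernia, of which 2 were not occluded and 3 were occluded. The score was read in the other 5 libraries. Genes with a gap of at least 2-fold between 2 sets of libraries were counted over every possible split.

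The edgeR test was tested on simulated data with 200 changed genes among 13379. For hernia with occlusion against hernia it recovered 39% of genes changed 2-fold and 82% of genes changed 4-fold, with 11 false calls among 132. DESeq2 1.42.0, run on the same simulated counts, recovered 54% and 85%, with 52 false calls among 191. For hernia against control, edgeR recovered 37% and 74%, with 7 false calls among 118. DESeq2 there recovered 57% and 82%, with 42 false calls among 181. Alternatives comprised limma 3.58.1 on log2 CPM scaled by the total count alone, with pseudocounts of 0.1, 0.5 and 2, other filters and scalings, array weights, DESeq2, fits of the compared groups alone, and leaving out each library. Limma on log2(CPM + 0.5), DESeq2, scaling by the total count alone, the fit without the occlusion group and leaving out libraries of groups outside a comparison were added after the data were seen.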

Results

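Messenger RNA was sequenced from the left upper lobe of rabbit fetuses in a surgical model of congenital diaphragmatic hernia, a defect in which abdominal organs enter the chest and the lung stays small. A left hernia was made at embryonic day 25. Tracheal occlusion, which traps lung fluid and stretches the lung, was done at embryonic day 27. Lungs were collected at E30.5. The 10 libraries comprised 3 controls, 2 with a hernia, 2 with occlusion and 3 with a hernia followed by occlusion. Total counts over the 13429 genes were 18.1, 19.9 and 17.5 M in controls, 16.4 and 22.2 M with a hernia, 19.8 and 17.6 M with occlusion, and 19.3, 19.4 and 18.9 M with both, and between 18 and 35 genes stood at 0 in a library. The most abundant gene held between 1.28% and 3.08% of a library's counts.

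Libraries of the same group were hardly more alike than libraries of different groups. Log2 expression correlated across genes at a median r of 0.974 over the 8 pairs within a group and 0.967 over the 37 pairs between groups. The closest pair was controls 1 and 3 (r = 0.992), whose counts still differed far beyond sampling noise (chi-square per degree of freedom 13.8). The least alike pair within a group was occlusion replicates 1 and 2 (r = 0.952). The first principal component, with 33.8% of the variance, placed occlusion replicate 1 at 35.2, hernia with occlusion replicate 1 at 31.2 and replicate 3 at 44.3. The 5 libraries without occlusion ran from -30.6 to -5.2. Occlusion replicate 2 lay inside that range, at -22.1, and hernia with occlusion replicate 2 lay just above it, at -4.4. Occluded libraries averaged 33.7 higher than the others on this component (two-sided exact permutation p = 0.0556, adjusted p = 0.222 over 8 tests). On the second component libraries with a hernia lay lower than those without, with a mean difference of -22.9 (two-sided exact permutation p = 0.0317, adjusted p = 0.222). Neither difference passed the correction.

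**Figure D1:**
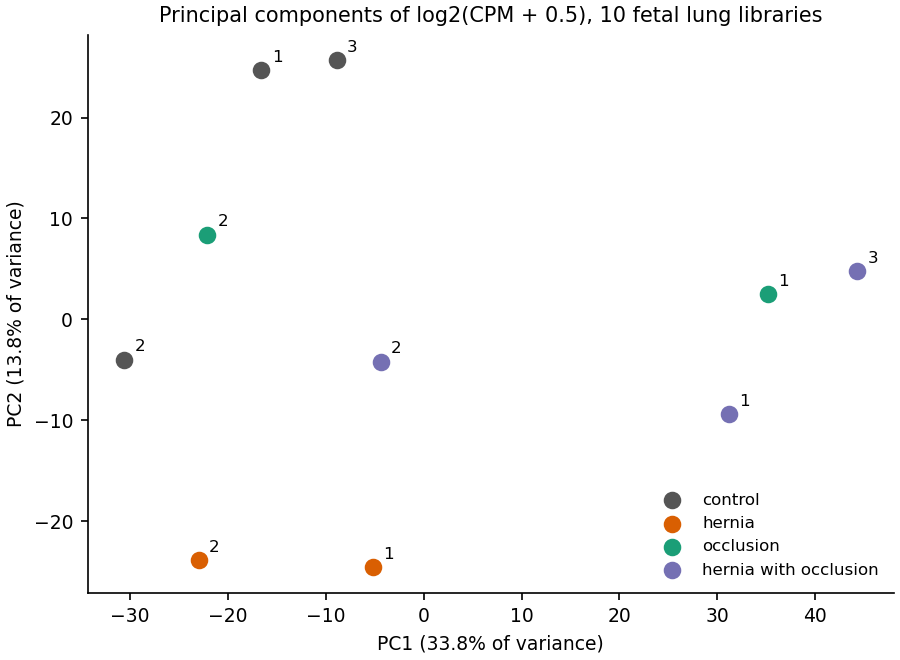
First and second principal components of log2(CPM + 0.5) over 13379 genes; each point is a library, coloured by group and numbered by replicate. Occlusion replicate 1 and hernia with occlusion replicates 1 and 3 lie between 31.2 and 44.3 on the first component, and the other 7 libraries lie below 0.

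The comparison of hernia with control asks what the hernia alone changed in the fetal lung. The title stems of the hernia libraries, M38 and M39, also lie apart from those of the controls, and the 2 differences cannot be told apart. ENSOCUG00000001536 rose 4.13-fold, from 8.63 ± 1.7 CPM (SD, n = 3) in controls to 35.7 ± 8.4 CPM (SD, n = 2) with a hernia. Its log2 change was 2.05 ± 0.19 (SE), with an edgeR adjusted p of 0.0206, and it was the only gene called. ENSOCUG00000009644 stood at 150 ± 16 CPM (SD, n = 3) in controls and at 30 ± 8.1 CPM (SD, n = 2) with a hernia, a log2 change of -2.33 ± 0.27 (SE) that did not pass (edgeR adjusted p = 0.0654). ENSOCUG00000025949 was nearly silent in controls, between 0.17 and 0.893 CPM, and reached 102 and 186 CPM in the hernia libraries, a log2 change of 8.20 ± 1.26 (SE) that did not pass either (edgeR adjusted p = 0.124). It did not follow the hernia alone, since it stood at 73.2 CPM in occlusion replicate 1 and at 2.54 CPM in occlusion replicate 2, neither of which had a hernia. At an unadjusted p under 0.05 there were 637 genes higher and 801 lower, where chance gives 669 in all on average. Every hernia library lay above every control in 17.9% of genes and below in 17% of genes, where chance gives 10% each on average. Genes vary together, so chance values can lie far from these averages, here and in the comparisons below. The counts in other splits of the libraries, given under other observations, show this. DESeq2 called 51 genes higher and 97 lower. The edgeR call was lost without control 1, control 3, hernia replicate 2, or hernia with occlusion replicate 1 or 3 (adjusted p up to 0.194). Without occlusion replicate 1, occlusion replicate 2 or hernia with occlusion replicate 2, edgeR called 16, 17 and 3 genes. ENSOCUG00000009644 passed without any of these 3 libraries (edgeR adjusted p = 0.0302, 0.0346 and 0.0188; 6.67e-16 to 0.421 over 24 alternatives). ENSOCUG00000025949 passed without either occlusion library (edgeR adjusted p = 0.00121 and 0.00105; 1.04e-07 to 0.583 over 24 alternatives).

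Occlusion against control asks what occlusion changed in a lung without a hernia. ENSOCUG00000027099 fell to 2.59 ± 0.43 CPM (SD, n = 2) from 108 ± 34 CPM (SD, n = 3), a log2 change of -5.39 ± 0.54 (SE) with an edgeR adjusted p of 0.0203. ENSOCUG00000001536 rose 4.8-fold to 41.5 ± 4 CPM (SD, n = 2), with an edgeR adjusted p of 0.00883. These were the 2 genes called. At an unadjusted p under 0.05 there were 433 genes higher and 253 lower, close to the 669 that chance gives. Occluded libraries lay entirely above controls in 10.2% of genes and entirely below in 10.3%, against 10% each by chance. DESeq2 called 12 genes higher and 10 lower. The 2 occlusion libraries differed from each other more than any other pair within a group. The call of ENSOCUG00000027099 was lost when any single control, hernia or occlusion library or hernia with occlusion replicate 2 was left out (adjusted p from 0.0501 to 0.122), and under limma with array weights. That of ENSOCUG00000001536 was lost without control 1 or 3, and in a fit of these groups alone (adjusted p up to 0.0931). Without occlusion replicate 1 or 2, edgeR called 8 and 9 genes.

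Hernia with occlusion against hernia compares treated with untreated hernia lungs. Here too the untreated libraries differ in title stem, so a difference of stem cannot be told apart from occlusion. ENSOCUG00000027099 fell again, to 2.73 ± 1.6 CPM (SD, n = 3) from 96.2 ± 5.7 CPM (SD, n = 2), a log2 change of -5.14 ± 0.46 (SE) with an edgeR adjusted p of 0.0152. ENSOCUG00000009644 stood at 124 ± 38 CPM (SD, n = 3) after occlusion, near the 150 ± 16 CPM (SD, n = 3) of controls, with a log2 change of 2.05 ± 0.26 (SE) from the hernia group that did not pass (edgeR adjusted p = 0.0867). ENSOCUG00000025949 stood between 0.306 and 1.06 CPM in hernia with occlusion, against 102 and 186 CPM in the hernia group and 73.2 and 2.54 CPM with occlusion alone (log2 change -7.69 ± 1.21, edgeR adjusted p = 0.0867). ENSOCUG00000027099 was the only gene called by edgeR. At an unadjusted p under 0.05 there were 1401 genes higher and 1259 lower, together 2660, the most of the 8 comparisons. Groups did not overlap in 20.8% of genes upward and 20.1% downward, against 10% each by chance. DESeq2 called 471 genes higher and 371 lower. Without occlusion replicate 1 or 2, which take no part in the comparison but enter the shared estimate of spread, edgeR called 418 and 439 genes. Without hernia replicate 1 there were 3 calls, and without hernia with occlusion replicate 1 or 2 there were 2 and 7. In these fits ENSOCUG00000009644 passed without occlusion replicate 1 or 2 (edgeR adjusted p = 0.0291 and 0.0294; 5.26e-12 to 0.29 over 24 alternatives), as did ENSOCUG00000025949 (0.00129 and 0.00114; 7.37e-07 to 0.343). ENSOCUG00000009644 also passed without hernia with occlusion replicate 2 (edgeR adjusted p = 0.0353). The call of ENSOCUG00000027099 was lost without control 3 or hernia replicate 2 (adjusted p up to 0.0695).

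**Figure D2:**
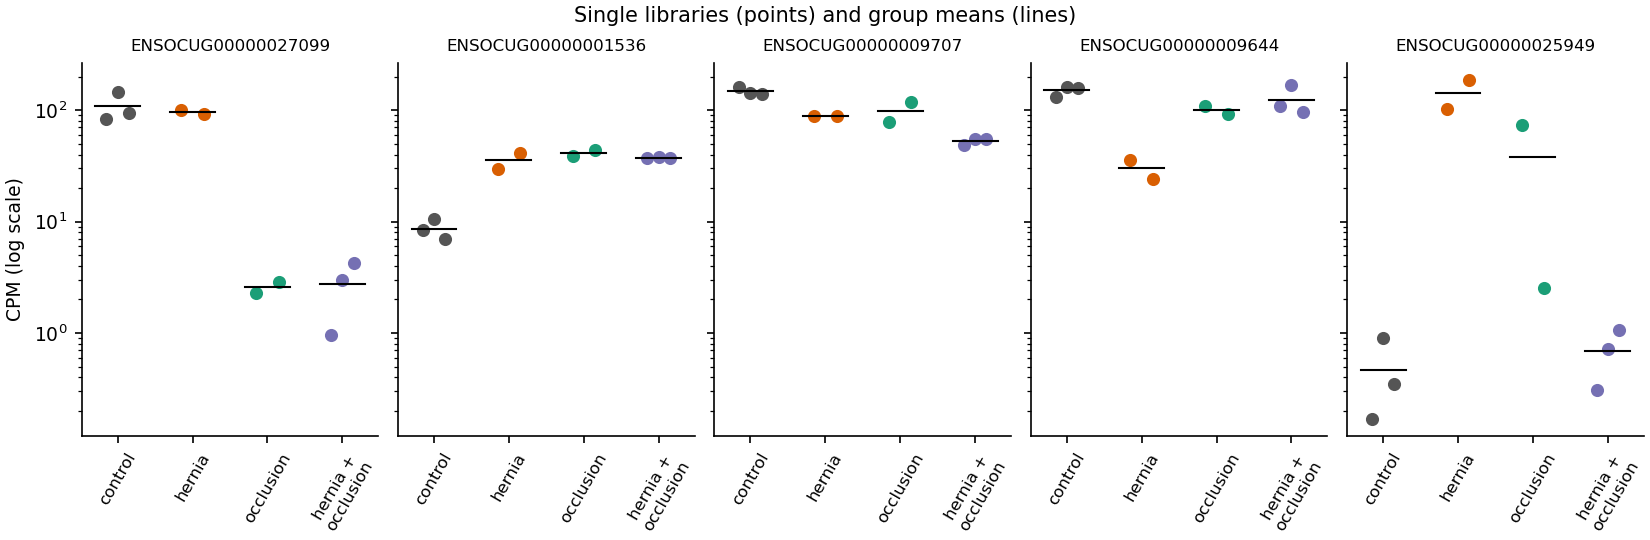
CPM on a log scale of 5 genes in each library (points) with the group mean (line), for the 4 groups. ENSOCUG00000027099 is between 0.969 and 4.23 CPM in the 5 occluded libraries and between 83.2 and 147 CPM in the 5 others; ENSOCUG00000001536 is lowest in the 3 controls.

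Hernia with occlusion against control asks how far the treated hernia lung still differed from a control lung. The labels do not say whether controls had a sham operation. ENSOCUG00000001536 was higher, at 37.3 ± 0.45 CPM (SD, n = 3) against 8.63 ± 1.7 CPM (SD, n = 3), a 4.31-fold rise. ENSOCUG00000027099 fell by 5.31 on the log2 scale. The edgeR adjusted p was 0.0046 for both. ENSOCUG00000009707 fell from 149 ± 10 to 53 ± 3.4 CPM (SD, n = 3 each), with an edgeR adjusted p of 0.0134. It stood at 89.4 ± 0.28 CPM (SD, n = 2) with a hernia alone and at 98.4 ± 29 CPM (SD, n = 2) with occlusion alone. These 3 genes were the calls. Unadjusted p under 0.05 was reached by 1112 genes upward and 954 downward. Groups of 3 did not overlap in 11.6% of genes in each direction, against 5% by chance. DESeq2 called 217 genes higher and 249 lower. Of the 3 calls, that of ENSOCUG00000001536 was lost without control 1, and that of ENSOCUG00000009707 without control 1 or 3 or hernia with occlusion replicate 1 or 3 (adjusted p up to 0.119). There was 1 call without control 1, and there were 11 without control 2, 13 and 12 without occlusion replicates 1 and 2, and 8 without hernia with occlusion replicate 2.

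Against occlusion alone, hernia with occlusion gave no gene past the edgeR threshold. There were 633 genes at an unadjusted p under 0.05, with 162 higher and 471 lower, fewer than the 669 of chance, and DESeq2 called 4 higher and 22 lower. Without occlusion replicate 1 edgeR called 68 genes, and without replicate 2 it called 4. It called 1 gene without hernia replicate 1, hernia replicate 2 or hernia with occlusion replicate 1. The hernia effect averaged over occlusion status also gave no edgeR call, with 764 genes at an unadjusted p under 0.05, and DESeq2 called 77. Without occlusion replicate 1 the averaged hernia effect had 51 edgeR calls, without control 2 it had 2, and without hernia with occlusion replicate 1 it had 1. The interaction, which tests whether occlusion acted differently in lungs with and without a hernia, had 0 edgeR calls, 1324 genes at an unadjusted p under 0.05 and 66 DESeq2 calls. It had 11 edgeR calls without occlusion replicate 1, 6 without replicate 2 and 1 without hernia with occlusion replicate 1. The interaction of ENSOCUG00000001536 was -2.20 ± 0.26 (SE, log2; edgeR adjusted p = 0.0803), since its level after both operations was near that after either. For ENSOCUG00000009644 the interaction was 2.63 ± 0.36 (edgeR adjusted p = 0.098), and for ENSOCUG00000025949 it was -13.97 ± 1.72 (edgeR adjusted p = 0.0803). The value of ENSOCUG00000025949 rests on occlusion libraries of 73.2 and 2.54 CPM, and was -10.07 without occlusion replicate 1 and -14.91 without replicate 2. None of the 3 interactions passed in edgeR with all libraries, and all 3 passed in DESeq2. Leaving out occlusion replicate 1, ENSOCUG00000001536 (edgeR adjusted p = 0.0491; 1.14e-09 to 0.476 over 22 alternatives) and ENSOCUG00000025949 (0.023; 1.64e-11 to 0.482) passed, and without replicate 2 ENSOCUG00000025949 did (0.000133). For ENSOCUG00000009644 the adjusted p over 22 alternatives ran from 9.16e-10 in DESeq2 to 0.482.

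Averaged over hernia status, ENSOCUG00000027099 was 38.41-fold lower in occluded than in other lungs, with an edgeR adjusted p of 0.00159. The labels give neither genotype nor sex of the fetuses. The lowest library without occlusion had 1470 counts of this gene, and the highest occluded library had 80. This was the only call, and it held under all 22 alternatives run. Unadjusted p under 0.05 was reached by 1297 genes upward and 942 downward, and DESeq2 called 226 higher and 183 lower. Without occlusion replicate 2 edgeR called 909 genes, without replicate 1 it called 10, and without hernia with occlusion replicate 2 it called 11. It called 3 without control 2, hernia replicate 1 or hernia replicate 2, and 2 without control 3 or hernia with occlusion replicate 1. The occlusion effects in lungs without and with a hernia, which share no library, correlated at r = 0.29 (rho = 0.24) across 13379 genes. The sign was the same in 56.1% of genes. Simulated unchanged groups, with genes drawn independently, gave r between -0.05 and 0.04. The jackknife standard error of r over libraries was 0.36, larger than r itself. The value rests on occlusion replicate 1, since it was 0.4 with that library alone and -0.02 with replicate 2 alone. Leaving out hernia replicate 2 gave 0.15 and hernia with occlusion replicate 3 gave 0.17. DESeq2 calls in the 2 comparisons shared 1 gene higher and 2 genes lower, where independent lists share 0.5 and 0.33. The hernia effects without and with occlusion, which also share no library, correlated at r = 0.04 (rho = -0.1), where simulated unchanged groups gave -0.04 to 0.04. The sign was the same in 43.5% of genes, against a simulated mean of 50%, and the jackknife standard error of r over libraries was 0.11. This second correlation was added after the data were seen. The occlusion score was 0.48, 0.47 and 0.52 in the controls, 1.01 in occlusion replicate 1 and 0.35 in occlusion replicate 2 (log2). The libraries used to choose its genes had -0.62 and -0.51 with a hernia and 1.3 to 1.53 with hernia and occlusion. Controls lay between them, so the score may follow the hernia as well as occlusion. Against the control mean, 87.2% of the score genes in replicate 1 and 25.5% in replicate 2 lay on the side seen after occlusion in hernia lungs.

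**Figure D3:**
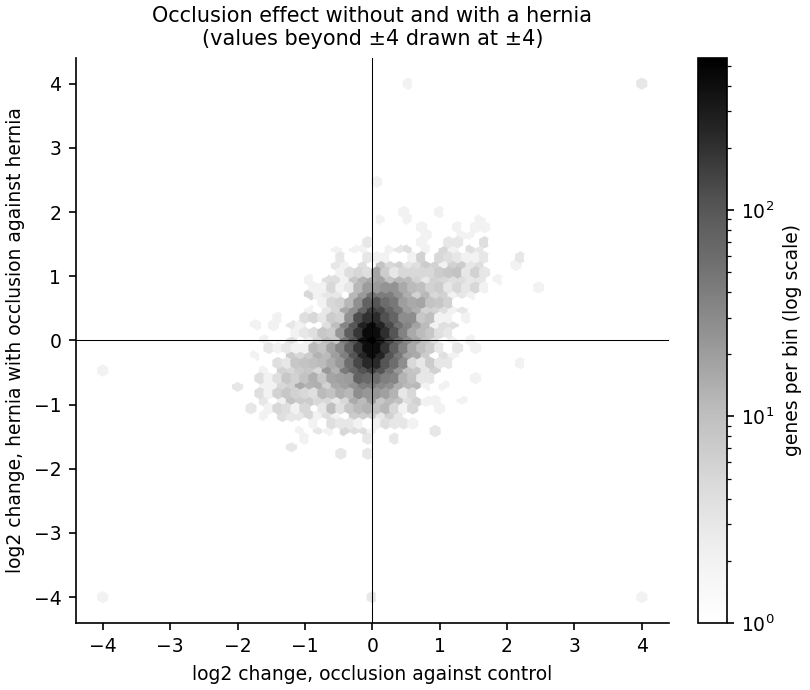
Log2 change of each of 13379 genes after occlusion without a hernia (horizontal axis) and with a hernia (vertical axis), from edgeR, as the number of genes per bin. Most genes lie near 0, and the remaining genes lean along the rising diagonal (r = 0.29 on log2 CPM means).

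**Figure D4:**
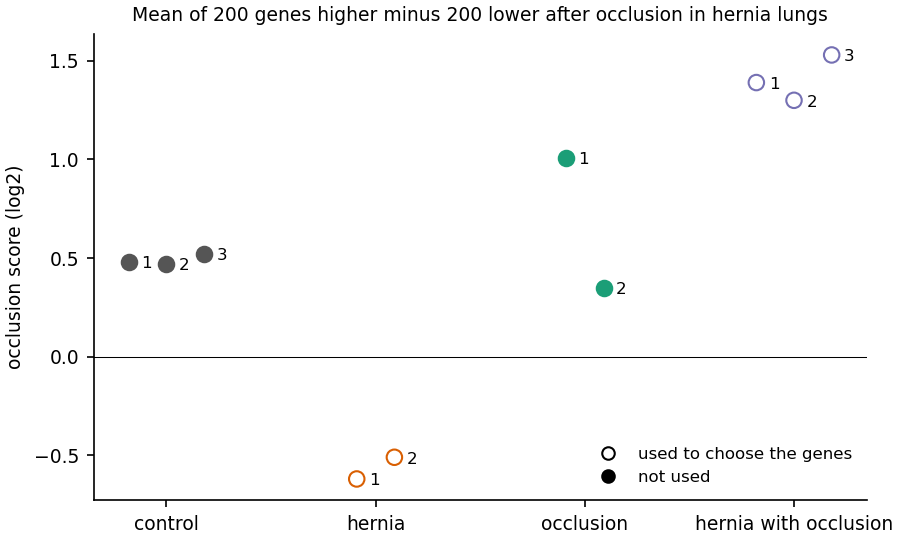
Occlusion score of each library, the mean log2 CPM of 200 genes higher minus that of 200 genes lower after occlusion in hernia lungs; open points were used to choose the genes. Occlusion replicate 2, at 0.35, lies below the controls and replicate 1, at 1.01, above them.

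The treated group also allows the question whether genes that differed with a hernia returned to the control level after occlusion. The hernia libraries differ in title stem from the control and the treated libraries, so a return cannot be told apart from a difference of stem. The gene called by edgeR, ENSOCUG00000001536, was also called in the treated group, with a log2 change from control of 2.05 with a hernia and 2.11 with hernia and occlusion. The remaining share of its change was 1.03. Over the genes called without occlusion replicate 1, occlusion replicate 2 or hernia with occlusion replicate 2, the median share was 0.18, 0.12 and 0.24. Another list held the 100 genes with the lowest p for hernia against control in limma on log2(CPM + 0.5) with scaled library sizes. Among them, the change from control in the treated group was a median 0.26 of that in the hernia group, also from limma. Simulated unchanged groups gave between 0.34 and 0.49, because both changes use the same controls. These simulations drew each gene independently, so their ranges leave out variation that libraries share across genes and may be too narrow. Of the 100 genes, 93% lay closer to control in the treated group, where simulations gave between 87% and 100%. Across all genes, the changes of hernia and of hernia with occlusion from control correlated at r = 0.38, against 0.4 to 0.5 in simulations. Their covariance was 0.0664, above the 0.0387 to 0.0495 of the simulations (mean 0.044). The hernia change and the change from hernia to treated hernia correlated at r = -0.49, a value that the shared hernia libraries alone exceed in size, at -0.63 to -0.56 in simulations. That covariance was -0.0902, larger in size than the -0.0721 to -0.0599 of the simulations (mean -0.0653). Correlation and covariance thus lie differently against the simulations, whose ranges may be too narrow. With 3 controls and 2 hernia libraries, no shared group could be split with at least 2 libraries on each side, so part of each value may come from the shared libraries. A measure that shares no library, the change from occlusion to hernia with occlusion over the change from control to hernia, had a median of -0.07 in the same 100 genes, against -0.09 to 0.16 in simulations.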

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

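DESeq2, limma at a pseudocount of 0.5, scaling by total count, the fit without the occlusion group, leaving out libraries of groups outside a comparison, and the agreement of the hernia effects with its alternatives were chosen after the results were seen. So were the named genes. Calls are given in the order hernia against control, occlusion against control, hernia with occlusion against hernia, against control and against occlusion, interaction, averaged occlusion and averaged hernia effect; edgeR on all libraries gave 1, 2, 1, 3, 0, 0, 1 and 0. No filter, a minimum of 5 CPM, median of ratios scaling, scaling by total count and a fit without abundance trend left each of these counts as it was. DESeq2 called 148, 22, 842, 466, 26, 66, 409 and 77. On simulated counts DESeq2 also made more false calls than edgeR, with 42 against 7 for hernia against control. Limma with array weights called 70, 1, 786, 1206, 0, 0, 1 and 0. Fits of the compared groups alone called 12, 1, 9, 6 and 0 in the first 5 comparisons. The fit without the occlusion group called 19 for hernia, 438 for hernia with occlusion against hernia and 12 against control. Limma gave 2 calls for hernia against control with a pseudocount of 0.1 or quantile normalization, and 3 with a pseudocount of 0.5 or 2 or with the title stem as a random effect (estimated correlation -0.35). With quantile normalization the averaged occlusion effect had 2 calls. Other counts under these limma fits were as in edgeR. Without the occlusion group the common biological coefficient of variation was 0.217, against 0.238 with all libraries; the cause of the other differences was not tested.

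Leaving out 1 library gave 0 to 17 calls for hernia, 0 to 9 for occlusion, 0 to 439, 1 to 13 and 0 to 68 for hernia with occlusion against hernia, control and occlusion, 0 to 11 for the interaction, 1 to 909 for averaged occlusion and 0 to 51 for averaged hernia. Where it left a group with 1 library, that library was assumed to vary like the others. The correlation of the occlusion effects ran from -0.02 without occlusion replicate 1 to 0.4 without replicate 2, and that of the hernia effects from -0.04 to 0.07. The share of the hernia change that remained after occlusion, over the genes called for hernia, was 1.03 for the 1 gene called by edgeR. It was 0.58 with limma at a pseudocount of 0.1 or with quantile normalization, 0.12 at 0.5, 0.13 at 2 or with the title stem, 0.32 with array weights, 0.27 with DESeq2 and 0.12 without the occlusion group, because other genes were called. Leaving out a library gave 0.12 to 1.03 for the 5 libraries without which edgeR still called a gene for hernia; without any of the other 5 there was no such gene and no value. In the comparisons where the text gives their calls or their missed thresholds, the named genes kept their direction under each alternative run. ENSOCUG00000009644 passed for hernia against control in 12 of 24 alternatives, and ENSOCUG00000025949 in 6 of 24. The gene list tests and the sums per gene symbol were not run, because no identifier had a symbol. At these depths the called genes had at least 19 counts in each library; at the lowest counts, in the occluded libraries for ENSOCUG00000027099, counting error adds to the differences between fetuses.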

Other observations

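The tests in this part were chosen after the results were seen, except those of the gap of single genes over splits and of fetal genotype or sex, which were stated before their outcome was known.

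ENSOCUG00000025949, high in both hernia libraries and occlusion replicate 1, had a small set of genes with a like profile. Another 4 genes were picked because they followed it over the 10 libraries at r over 0.95 on log2 CPM, so their likeness to it is no separate evidence. Together these 4 summed to 68.8 and 156 CPM in the 2 hernia libraries and 56.5 CPM in occlusion replicate 1. They summed to 4.28 CPM in occlusion replicate 2, to between 2.13 and 2.94 CPM in controls and to between 1.49 and 2.17 CPM in hernia with occlusion. Genes more than 2-fold above all 9 other libraries were most frequent in occlusion replicate 2, with 52, and control 2, with 41. Genes more than 2-fold below all others were most frequent in hernia with occlusion replicate 3, with 86, while the other libraries had between 1 and 10.

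Occlusion replicate 2 stood apart from occlusion replicate 1. On the occlusion score replicate 1 had 1.01 and replicate 2 had 0.35, below the controls. That score also sets the hernia libraries below the controls, so it may not measure occlusion alone. Its depth of 17.6 M counts lay inside the range of the other libraries, which argues against depth. The library with the same title stem deviated the other way from its group (r = -0.24). That 1 pair showed no shared deviation, but its differences also run along the first principal component, so it cannot decide on the stem. Whether the lung of occlusion replicate 2 was effectively occluded stays open. This library carried ENSOCUG00000027099 at 2.89 CPM, like the other occluded libraries, but single switch-like genes also follow no treatment here. A difference between fetuses is untested. The spread between the 2 occlusion libraries may account for the few edgeR calls elsewhere, since hernia with occlusion against hernia had at least 418 calls without either of them and at most 7 without any other library.

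ENSOCUG00000027099 separated the 5 occluded from the 5 other libraries by a gap of 17.7-fold on the scale of CPM + 0.5. Only 2 of the 126 splits into 5 and 5, the real one included, held a gene with as large a gap, and the largest in another split was 223-fold. In a fit without the occlusion group its edgeR adjusted p was 0.00614. Yet 9 other genes, ENSOCUG00000025949 among them, had gaps at least as large in 7 other splits. These were among 456 splits with at least 3 libraries on each side, and none is that of a treatment over all libraries. The 223-fold gap set control 2, occlusion replicate 2 and the hernia with occlusion libraries above the others. That split parts hernia with occlusion from hernia fully, so in that comparison a difference that follows it cannot be told apart from occlusion. For ENSOCUG00000027099, a genotype or sex of the fetuses that happens to follow occlusion cannot be told apart from an effect of occlusion, because neither is labelled.

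ENSOCUG00000001536 was higher in all 7 libraries with a hernia, occlusion or both, called operated here, than in all 3 controls, and the lowest operated library stood 2.84-fold above the highest control. The control and the operated library that share the title stem M83 differed by 3.53-fold, which argues against the stem. A gene with as large a gap was found in 21 of the 120 splits into 3 and 7, so that a gap of this size alone does not set the split by operation apart. A batch of library preparation that parts controls from operated fetuses cannot be told apart from the operation, since the labels give no batch.

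The counts of calls were set against those of other splits of the same libraries. For hernia with occlusion against control, the real split had 3 calls and the highest other 1, and 2066 genes at an unadjusted p under 0.05 against at most 1034; with 1 of 10 splits the real one, these are too few for a share under 0.05. For the averaged occlusion effect, 12 of 100 splits gave as many calls as the real 1, with up to 153, and 6 of 100 gave as many genes at an unadjusted p under 0.05 as the real 2239, with up to 3588. For the averaged hernia effect, 31 of 100 splits reached the real 764 genes at an unadjusted p under 0.05, with up to 3370. Chance is thus not excluded for these counts of the averaged effects. The 0 edgeR calls of the averaged hernia effect allow no such test, since 100 of 100 splits reach 0 by construction, and the highest other had 419; DESeq2 called 77. In the averaged effects, the splits with the most calls set occlusion replicate 1 and hernia with occlusion replicates 1 and 3 on one side. In these 3 libraries 82 genes were at least 2-fold higher and 1 at least 2-fold lower than in all others. All 3 were occluded, so a response to occlusion in part of the occluded lungs cannot be told apart from another structure of the samples. Splits that keep these libraries together may carry such a response, so their counts are no clean measure of chance.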
